A study of Mus musculus with 8 samples.

How the data were processed

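RNA of macrophages from LPS-treated wild-type and EP2 knockout mice had been hybridised to 8 1-colour Agilent arrays, 4 per genotype (WT 1 to 4 and EP2KO 1 to 4). Per the labels' protocols, 0.5 µg of total RNA was amplified and labelled with Cy3. The deposited scanner files hold each spot's intensity on a linear scale. Per the file headers these were extracted with Feature Extraction 10.7.1.1, whereas the submitters' processing notes name Agilent Feature Extraction 9.1. Their processed signal is already background-corrected, per the file headers, but not scaled between arrays. The deposited series table holds intensity values that were identical to that processed signal (largest log2 difference 0), so no log scale or centring had been applied to it. Its column medians ran from 52.6 (WT 2) to 96.9 (WT 3).

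From these files the log2 of the processed signal was taken and each array's 75th percentile was subtracted. Of 44397 spots per array, 1377 control spots were left out, spots with an outlier flag were set missing, and spots of 1 probe were averaged (399 probes had 10 spots each), which gave 39429 gene probes. Probes were named through the RefSeq transcripts of a gene table of assembly GRCm38.p6, which named 27508 probes and left 11921 unnamed; the array's design states mm9, so no coordinates are given and the table served for names and gene order only. A probe was kept when it was well above background on all arrays of at least 1 genotype. The brightest kept probe stood for a gene, and an unnamed probe for itself, which left 20736 tested features (14491 named genes and 6245 unnamed probes). Of the 3700 genes with several kept probes, 0 had 1 probe over 1 higher and another over 1 lower on the log2 scale. Probes of 1 gene can still differ in size. Where a probe was not well above background on any array of a genotype, its fold is a bound, "at least N-fold": the brighter group's mean against, per array, the higher of the dim value and the lowest signal among probes well above background.

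Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment, two-sided, at an adjusted p of 0.05. Differences are EP2KO minus WT on the log2 scale, with the standard error (SE) of the limma fit, and n = 4 arrays per genotype. The 28 gene lists were tested with camera at its preset correlation of 0.01, adjusted over the lists, on the 20705 features with no missing value. Of 899 names written on the lists, 896 matched a symbol, and a list needed 5 measured members. Design, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took Ptger2, then the 12 named genes per direction with the largest difference among those past the threshold with separated groups, or where fewer passed, all of these and the smallest unadjusted p up to 5 per direction, given as values. From each list it took up to 4 members with the largest difference past the threshold, or where none passed the 2 with the smallest unadjusted p. Not every gene the rule takes is used here. Other list members, the slide comparison, each slide alone, the neighbours of Ptger2 and 3 further marker lists were chosen after values had been seen.

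The arrays lay on 2 slides, scanned on different days, each with 2 arrays of either genotype, so slide and scan day coincide; a fit with the slide as a block and values within each slide accompany the main result. On both slides WT arrays held positions 1 and 2 and EP2KO arrays positions 3 and 4, so genotype and position cannot be told apart. Arrays of equal replicate number deviated together from their group means (r across genes 0.74, 0.12, 0.55 and 0.43 for numbers 1 to 4), but each such pair also shares a slide. Within slides the correlation was -0.39 on slide 1 and -0.10 on slide 2. By the rule set for pairing, every r above 0.1, the replicate number is also given as a block where it changes a call.

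Alternatives covered background correction, scaling, filters, choice of probe, blocks, array weights, variance model and each array left out. The background alternative (normexp, offset 50) was planned on the mean spot signal and run on the median spot signal, since the scanner files hold no column of mean spot signal. The planned test of called genes by distance from Ptger2 was not run, because the builds differ and no named gene was called without a slide term; gene order took its place. The slide as a random block (duplicateCorrelation, correlation 0.579) had been planned only for slides with 1 genotype each. It was run after the data had been seen, for genes only, since camera takes no random block.

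The fits were tested on simulated data: 5 sets of 20705 features with the real means, slide differences and residual spread, and 200 changed features each. For EP2KO against WT the fit without a block recovered 24.4% of 2-fold, 64.0% of 4-fold, 79.6% of 8-fold and 95.6% of 64-fold changes. The slide-blocked shares were 58.4%, 86.0%, 94.4% and 98.8%. False calls were 3 of 662 without and 47 of 891 with the block. Noise was independent between features, and no slide effect that differs between genotypes was simulated, so these shares can differ on the real arrays. The camera test, slide in the model, found 20 of 20 lists of 30 genes shifted by 0.5 and called 0 of 20 unshifted lists; these simulated genes were independent, unlike real list members.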

Results

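The data were 8 whole-genome expression arrays of macrophages from mice given LPS, a bacterial endotoxin that activates macrophages. There were 4 arrays of wild-type (WT) mice and 4 of mice lacking EP2 (EP2KO), a receptor for prostaglandin E2 encoded by Ptger2. The series title places the receptor in macrophage activity and cardiac repair. Between 25565 (WT 1) and 32156 (WT 3) of 39429 probes were well above background, and 0 spots were saturated. The 75th percentile of the signal ran from 987 (WT 2) to 1508 (WT 3). Probes spotted 10 times had a median SD between 0.05 and 0.07 log2 units within an array. The number of arrays limits the precision. The labels do not say that replicates came from separate mice, so p-values measure only the spread between these samples.

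The slide separated the arrays more than the genotype did. The first principal component held 61.0% of the variance and parted slide 1 (WT 1, WT 2, EP2KO 1 and EP2KO 2) from slide 2 (WT 3, WT 4, EP2KO 3 and EP2KO 4). Across genes, which are not independent replicates, arrays of 1 slide and genotype correlated at r = 0.980 to 0.995. Arrays of 1 slide but different genotype correlated at 0.969 to 0.987, and arrays of 1 genotype on different slides at 0.938 to 0.951. With genotype in the model, 8966 of 20736 features differed between the slides. Genotype differences did not run alike on the slides: across features their correlation was -0.22 (Spearman -0.26), and 36.3% had the same sign on both.

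**Figure D1:**
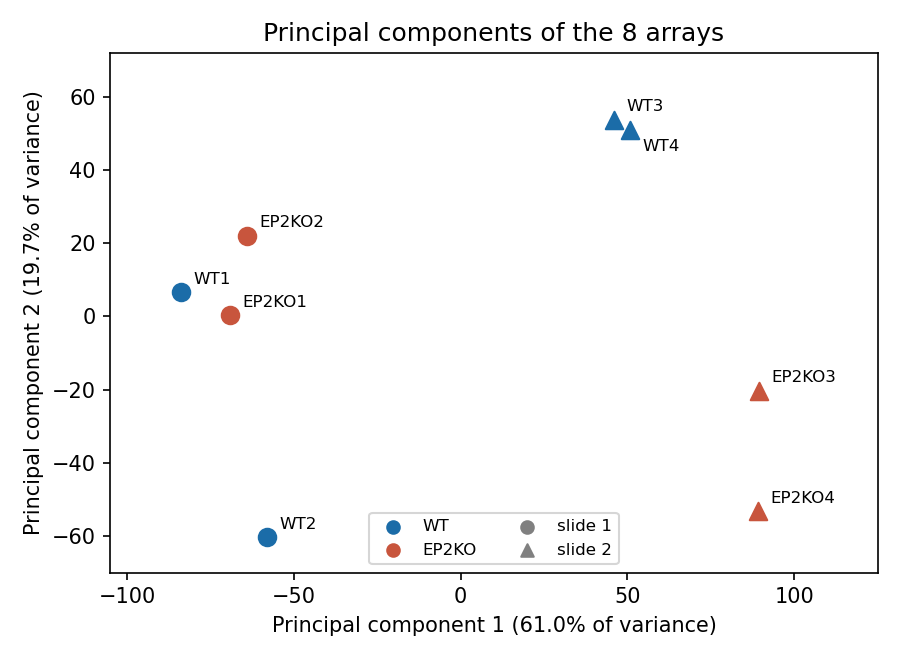
Principal components 1 and 2 of the 8 arrays, from log2 signals, with the share of variance on each axis; colour gives the genotype and shape the slide. Component 1 (61.0%) places slide 1 on the left and slide 2 on the right.

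Ptger2, the targeted gene, was lower in EP2KO on every array. Its signal, relative to each array's 75th percentile, was 0.97, 1.12, 0.90 and 1.00 on WT 1 to 4 and 0.36, 0.29, 0.32 and 0.22 on EP2KO 1 to 4. The log2 difference was -1.76 ± 0.17 (SE, n = 4 per genotype), a 3.39-fold lower signal. It was -1.71 on slide 1 and -1.82 on slide 2. An exact two-sided permutation test over 70 arrangements gave p = 0.0286, the smallest it can give. The limma adjusted p over all features was 0.0615, which misses the threshold, 0.0328 with the slide as a block and 0.217 with the replicate block. Ptger2 had 1 probe, well above background on all 8 arrays. Whether that probe lies in the deleted part is not given in the sources used here, so the remaining signal cannot be read as transcript of the intact gene, and the value checks the labels only if the probe does.

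In the comparison of EP2KO with WT, 2 unnamed probes rose and 0 features fell. Probe A_55_P2034481 was higher by 6.28 ± 0.48 and A_55_P1985422 by 6.43 ± 0.51 log2 units (SE, limma adjusted p = 0.0194 for both), and all 4 EP2KO values lay above all 4 WT values. The slide 1 and slide 2 differences were 7.06 and 5.49 for the first and 7.27 and 5.58 for the second. The gene table used here does not pair either probe with a gene. The array's own annotation gives A_55_P2034481 a RefSeq transcript that this gene table lacks. Signals of both probes rose and fell together from array to array, so they need not stand for 2 genes. At an unadjusted p under 0.05 there were 105 higher and 305 lower features, 1.98% of the 20736 tested. That is below the share of 0.05 that chance alone would give. This fit leaves the slide differences in its error, so its share cannot show whether further features changed. A fit with the slide as a block had 1523 features (7.34%) at an unadjusted p under 0.05. It called 4: both probes rose, and Ptger2 and the unnamed probe A_55_P2003488 fell. The latter differed by -1.82 ± 0.15, a value that rests partly on background, since it was not well above background on EP2KO 3 and EP2KO 4, both EP2KO arrays of slide 2; on slide 1 the difference was -1.65. With the replicate block the count was 0, with 1130 features (5.45%) at an unadjusted p under 0.05. Slide 1 alone, with 2 arrays per genotype, gave 0 of 21980 features (2837 unadjusted), and slide 2 alone 13 higher and 327 lower of 22921.

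Among named genes, none other than Ptger2 passed in either fit, and the values that follow did not pass. Rnase4, a secreted ribonuclease, was 3.56-fold higher in EP2KO (log2 1.83 ± 0.33). Supt16, a histone chaperone subunit, was higher by 0.80 ± 0.13. Clec1b, a C-type lectin receptor, was higher by 2.10 ± 0.45 and Frmpd1 by 1.36 ± 0.30. Asic5, an ion channel of the acid-sensing family, was at least 1.5-fold higher, being not well above background in WT. Cdhr1, a photoreceptor cadherin, was well above background on 4 WT and 0 EP2KO arrays and at least 5.0-fold lower in EP2KO (adjusted p = 0.0865). Samd4, an RNA-binding repressor of translation, was at least 5.56-fold lower by the same criterion, Nat8f5 at least 2.28-fold and Itln1, an intelectin, at least 2.03-fold. The non-coding gene 4930431P03Rik was lower by 1.64 ± 0.21 (log2 difference -1.64). All 10 differed in the same direction on both slides, which choosing genes by the smallest p over both slides favours. Supt16, Rnase4, Cdhr1 and Samd4 are among the 400 coding genes nearest to Ptger2 on chromosome 14 in GRCm38.p6 gene order.

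**Figure D2:**
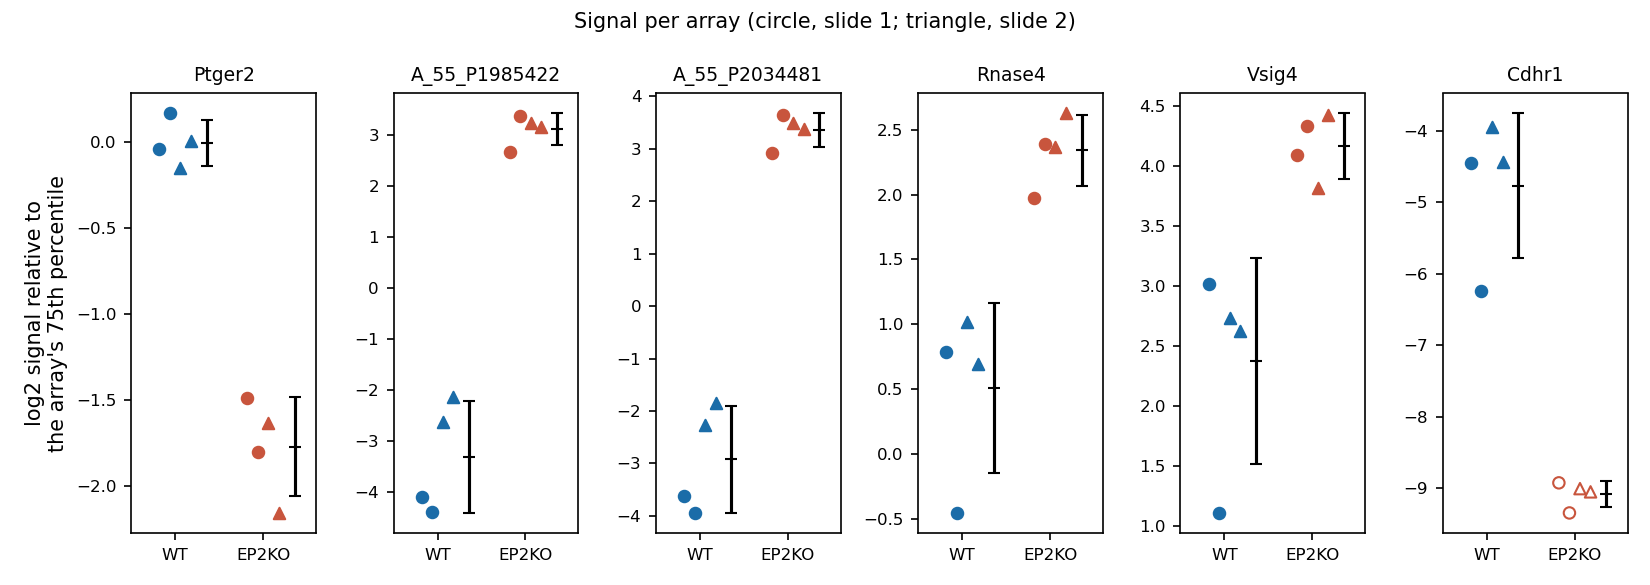
Signal on each array as log2 relative to the array's 75th percentile, for Ptger2, both called probes and 3 named genes that did not pass; circles are slide 1 and triangles slide 2. Open symbols are not well above background, and bars give the mean ± SD of the 4 arrays. EP2KO and WT values do not overlap in any of these panels.

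Marker genes of other cell types accounted for most of the lists called. With camera, 5 of the 28 lists were called: markers of large resident peritoneal macrophages and of eosinophils and mast cells rose, and those of T and NK cells, of fibroblasts and mesothelium, and chemokines fell. All 5 calls were lost with an estimated correlation (lowest adjusted p = 0.798) and with fry (lowest adjusted p = 0.936). As many lists were called in 31 of the 35 ways to split the arrays into 4 and 4, the real split included. In the slide-blocked fit 8 lists were called, adding lipid and cholesterol metabolism (up) and B cell and dendritic cell markers (down). Of these, 1 held with an estimated correlation, that of large peritoneal macrophages (camera adjusted p = 0.0286). With the slide as a block, not a planned setting for fry, fry called this list only (fry adjusted p = 0.0117). No member of any list passed over all genes or adjusted over the list alone without a slide term; with the replicate block 11 lists were called. Median and camera direction differed in sign for interferon, adhesion, alternative activation, neutrophil, erythroid and endothelial genes, none of them called, and median and mean for cAMP-responsive and matrix genes. In the slide-blocked fit members of lists not called passed too, adjusted over the list alone: 1 rose and 4 fell among monocyte and among neutrophil genes, and 2 rose and 3 fell among adhesion genes and chemokine receptors.

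Genes of large resident peritoneal macrophages were higher in EP2KO, with 20 of 25 measured members above 0 and a median log2 difference of 0.52 (camera adjusted p = 6.85e-07; with an estimated correlation the adjusted p was 0.798, and 0.0286 in the slide-blocked fit). The median was 0.87 on slide 1 and 0.60 on slide 2. Without EP2KO 2 the median over the remaining arrays was 0.22, and the list was not called. Ltbp1, a TGF-beta binding protein, was higher by 2.97 ± 1.16 and Naip1, an inflammasome sensor, by 0.89 ± 0.42 (0.37 by its other kept probe). In the slide-blocked fit, 10 members rose and 0 fell adjusted over the list alone. Among them were Timd4, a receptor for dying cells (1.63, slide 1 1.56 and slide 2 1.69), and Selp (1.73). Gata6, the transcription factor of these cells, was at -0.00, with 1.29 on slide 1 and -1.29 on slide 2.

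Eosinophil and mast cell genes had a median of 1.04 over 17 members (0.61 on slide 1, 0.73 on slide 2; camera adjusted p = 3.78e-06, with an estimated correlation the adjusted p was 0.798, and 0.279 in the slide-blocked fit). The list was called in 22 of 26 other ways of processing, and its median ran from 0.23 with normexp to 1.39 without WT 1. The mast cell proteases Mcpt4 (2.36 ± 1.02) and Tpsb2 (1.62 ± 0.74) had the smallest unadjusted p and did not pass. In the slide-blocked fit 9 members rose and 0 fell adjusted over the list alone. The eosinophil genes Siglecf (-0.05) and Ccr3 (0.13) were not among them.

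T and NK cell genes had a median of -0.76 over 32 members, 30 of them lower in EP2KO (camera adjusted p = 7.31e-07; with an estimated correlation the adjusted p was 0.798, and 0.308 in the slide-blocked fit). The median was -1.23 on slide 1 and -0.38 on slide 2. Lat, a T cell receptor adaptor, differed by -0.78 ± 0.22 and Bcl11b, a T lineage transcription factor, by -1.73 ± 0.93. Once the slide was a block, 22 members fell and 1 rose (Il7r, 0.52) adjusted over the list alone. B cell genes (median -0.36, 24 members) included Jchain at -3.88 ± 1.17, with -1.29 on slide 1 and -6.48 on slide 2, and Cd72 at -0.97 ± 0.68. Dendritic cell genes had a median of -0.33, with Cacnb3 at -1.41 ± 0.75 and Flt3 at -0.65 ± 0.42.

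Fibroblast and mesothelial genes had medians of opposite sign on the slides, and that of slide 1 rests on WT 2. The list median, centred per gene, was -1.59 on WT 2, while WT 1 (0.93) lay between EP2KO 1 (0.42) and EP2KO 2 (1.08). Their median was -1.07 over 33 members (camera adjusted p = 1.22e-06; adjusted p = 0.798 with an estimated correlation), made of 1.07 on slide 1 and -3.11 on slide 2. The lower value leans on EP2KO 4 (list median -2.76, against -0.70 on EP2KO 3): without it the slide-blocked median was -0.18. The list was called in 22 of 26 other ways of processing, not without WT 4, without EP2KO 4, with an estimated correlation or with fry. Igfbp6 differed by -1.85 ± 0.74 and the collagen-binding proteoglycan Dcn by -1.82 ± 0.98; Dcn was 0.40 on slide 1, where its signal was 4.71 on WT 1 and 2.82 on WT 2, and -4.05 on slide 2. Chemokines had a median of -0.32 over 22 members (camera adjusted p = 0.0140; adjusted p = 0.798 with an estimated correlation), with 0.28 on slide 1 and -0.95 on slide 2. This list was called in 16 of 26 other ways of processing, with a median from -0.77 to -0.18. Ccl12, a monocyte attractant, differed by -2.38 ± 0.83 (-0.51 on slide 1, -4.24 on slide 2). Cxcl5, a neutrophil attractant, differed by -2.84 ± 1.08 (-0.82 on slide 1, -4.86 on slide 2).

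LPS response and macrophage activation lists were not called. The inflammatory cytokine and mediator list had a median of -0.13 over 24 members (-0.17 on slide 1, -0.11 on slide 2), with Marcksl1 lower adjusted over the list alone in the slide-blocked fit (-0.82 ± 0.12) and with Nos2, the inducible nitric oxide synthase, at -0.72 ± 0.24 and Slc7a11 at 1.43 ± 0.56. Type I interferon response genes had a median of -0.06 over 35, with Ifi44 at -1.08 ± 0.34 and Irf7 at 0.41 ± 0.28. Alternative activation markers stood at 0.03 over 28, with the folate receptor Folr2 at -0.94 ± 0.24 (lower adjusted over the list alone in the slide-blocked fit, adjusted p = 0.0217) and Stab1 at -0.76 ± 0.38. Phagocytosis and scavenger receptors stood at 0.03 over 40, with the complement receptor Vsig4 at 1.80 ± 0.41. Dock2 was at -0.58 ± 0.24 (-0.27 by its other kept probe). Adjusted over the list alone in the slide-blocked fit, Vsig4, Timd4 and Cd93 rose and Axl fell. Antigen presentation genes had -0.17 over 34, with Nlrc5 at -0.43 ± 0.24 (-0.09 by its other kept probe) and Cd40 at -0.59 ± 0.37. The adhesion and chemokine receptor list stood at -0.04 over 32, with Itgb1 at 0.27 ± 0.14. Macrophage identity genes had 0.05 over 24 (-0.19 on slide 1, 0.42 on slide 2), with Adgre1, which encodes F4/80, at 0.32 ± 0.14 and Aif1 at -0.76 ± 0.42.

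The lists closest to the receptor were not called either. Prostanoid and leukotriene genes had a median of -0.18 over 31 members (-0.05 on slide 1, -0.28 on slide 2), with the prostaglandin D2 receptor Ptgdr2 at -0.88 ± 0.25 and Pla2g7 at 0.56 ± 0.18. Genes responsive to cAMP, the second messenger of EP2, had 0.02 over 39 (0.00 on slide 1, -0.04 on slide 2), with Thbs1 at 1.27 ± 0.54. Fosl2 was at -0.21 ± 0.12 (-0.50 by its other kept probe). Once the slide was a block, Thbs1, which encodes thrombospondin 1, was higher by 1.27 ± 0.13 (1.30 on slide 1, 1.24 on slide 2; limma adjusted p = 0.000811 over the list alone and 0.0616 over all features). Matrix and repair factors had 0.02 over 42 (0.60 on slide 1, -0.37 on slide 2), with the growth factor Pdgfb at -1.21 ± 0.25. Slide-blocked and adjusted over the list alone, Thbs1, Serpinb2 and Hgf rose and Pdgfb fell. Cell cycle genes had 0.09 over 42, with 1.42 on slide 1 and -1.01 on slide 2, and with Cenpa at 0.41 ± 0.31 and Kif23 at 0.52 ± 0.64.

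Metabolic and stress lists had medians near 0. Glycolysis and hypoxia genes stood at 0.02 over 39, with Egln3 at 0.56 ± 0.38 and Pdk1 at -0.33 ± 0.23. Oxidative phosphorylation stood at -0.06 over 45, with Cycs at -0.26 ± 0.17 and Ndufs8 at -0.34 ± 0.27. Lipid and cholesterol genes stood at 0.03 over 46 (0.12 on slide 1, 0.05 on slide 2), with Acaca at 0.56 ± 0.28 and Elovl6 at -0.28 ± 0.18. Heat shock and immediate early genes stood at -0.07 over 27, with Zfp36 at -0.42 ± 0.19 and Jund at -0.29 ± 0.13.

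The remaining cell type lists were not called in either fit. Monocyte genes had a median of -0.22 over 21 (F13a1 -0.61 ± 0.33), and neutrophil genes -0.08 over 24 (Ltf 0.91 ± 0.54, Cxcr2 -1.25 ± 0.84). Erythroid and platelet genes had -0.00 over 17 (Tal1 0.35 ± 0.15, Pf4 0.27 ± 0.18). Endothelial genes had -0.10 over 13, with 0.77 on slide 1 and -0.37 on slide 2 (Egfl7 1.11 ± 0.53, Ptprb -1.89 ± 1.09). Muscle genes had -0.13 over 17 (Myl4 -0.95 ± 0.49, Cox6a2 -0.66 ± 0.40), and adipocyte genes 0.09 over 8 (Fabp4 1.00 ± 0.83, Lpl 0.36 ± 0.56). Slide-blocked and adjusted over their lists alone, Fabp4 and Vwf rose, and Cox6a2, Cd72 (B cell list) and Thy1 (fibroblast list) fell.

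**Figure D3:**
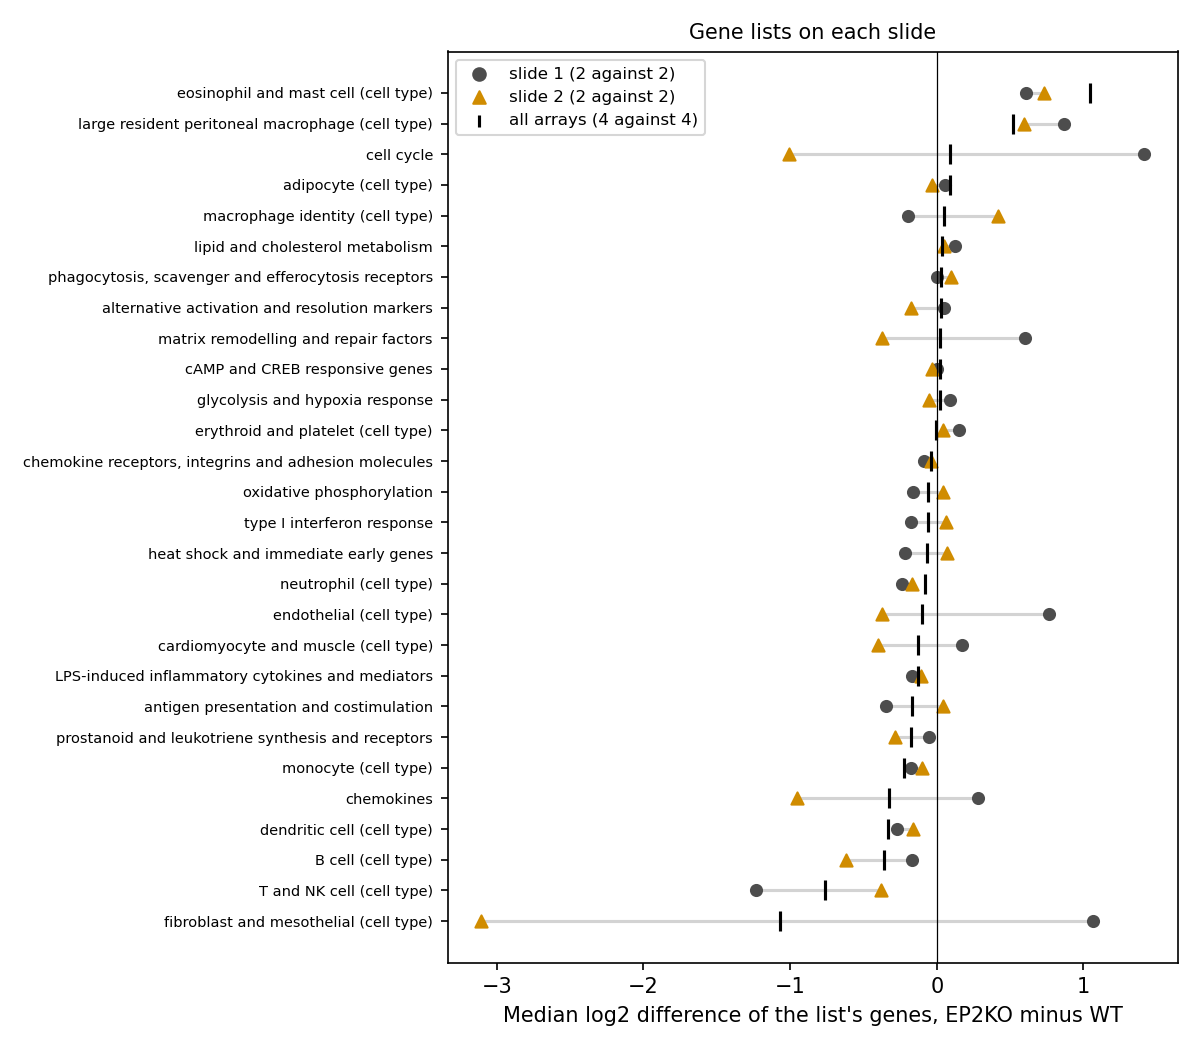
Median log2 difference (EP2KO minus WT) of the members of each of the 28 gene lists, on slide 1 (circles), slide 2 (triangles) and all arrays (bars). Fibroblast and mesothelial genes lie at 1.07 on slide 1 and -3.11 on slide 2, while T and NK cell genes lie below 0 on both.

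Genes of the sex chromosomes were measured as a check of the labels, which give all mice as male. Xist, the RNA that silences an X chromosome in females, was well above background on 8 of 8 arrays by both of its probes, with means of -0.36 ± 0.65 and -1.55 ± 0.60 (log2, SD, n = 8). The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, with 5 probes, were not well above background, except 1 Uty probe on 1 array.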

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

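The interaction test and the tests of the placement of genes near Ptger2 against chance and against the slides, that of genotype alone for the stromal genes, and both tests on the sex-linked genes were chosen after their results had been seen.

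A few values lay far from the other 3 arrays of their genotype, by the gap to the nearest array over the group's range. In WT these were Tal1 on WT 4 (ratio 0.974), Itgb1 on WT 2 (0.910), Jchain on WT 2 (0.876) and Elovl6 on WT 1 (0.866). The WT median of macrophage identity genes was 0.16 on WT 2 against -0.09 to -0.06 on the others (0.894). Among fibroblast and mesothelial genes it was -1.59 on WT 2 against 0.93 to 1.26 (0.883). These are 6 of 196 groups of 4 tested, where chance gives about 9.8 for values of 1 normal population. Each group here held 2 arrays of each of 2 slides, so 9.8 is no fair expectation and the counts cannot be compared.

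The genotype difference itself differed between the slides for 3 named genes by an interaction term in limma. It was lower on slide 2 by a log2 difference of -4.02 for Cldn10 (limma adjusted p = 0.0269) and -3.30 for Plvap (adjusted p = 0.0269), and higher by 3.31 for Lrmda (adjusted p = 0.0348). At an unadjusted p under 0.05 there were 4379 features, 21.1% of the 20736 tested, above the share of 0.05 that chance alone would give. Features are not independent, so this share is no test.

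Of the 25 named genes with the smallest p apart from Ptger2, 6 (Cdhr1, Supt16, Samd4, Rnase4, Ang and Pnp) are among the 400 coding genes nearest to Ptger2, against 211 of 14465 other named genes. Chance placement is argued against (one-sided Fisher's exact p = 1.47e-06). For 10 to 400 top genes the exact p ran from 3.45e-08 to 1.00e-05, and from 4.72e-08 to 0.00928 in the slide-blocked ranking. Among the nearest 100 genes only 1 of 25 lay (exact p = 0.0522), or 0 in the slide-blocked ranking. The test treats genes as independent. With 70, 77 and 78 genes between them and Ptger2, Pnp, Ang and Rnase4 may not be, so these p-values can overstate the evidence. A slide difference shared by both genotypes cannot have made these differences, since it cancels where each slide held 2 arrays of either genotype. The slide-blocked ranking, which held 4 of 25 (one-sided exact p = 0.000483), therefore adds nothing on this point. A slide effect that differs between genotypes stays open. Of these genes, 6 of 6 had the same sign on both slides, but a ranking over both slides favours such genes. The count was 1 of 25 on slide 1 alone and on slide 2 alone, and 3 with the replicate block. It was 3 without WT 1 or without WT 3, and 2 in the slide-blocked fit without WT 3. A candidate explanation is flanking DNA of another strain carried with the knockout allele, acting on expression or on probe binding; sequence differences under single probes stay open, since these genes had 0 other kept probes. The strains are not given in the sources used here, and no regulation by EP2 itself was tested.

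Fibroblast and mesothelial genes had a lower median in EP2KO without a slide term, with a higher one on slide 1 that rests on WT 2: the list median there was -1.59 on WT 2, while WT 1 (0.93) lay between EP2KO 1 (0.42) and EP2KO 2 (1.08). A varying share of stromal and mesothelial cells between samples is consistent with the members' median correlation within slide and genotype of 0.875, above 0.143 for the 95th percentile of 1000 random lists, though any co-regulated list could show this. The abundant members Sparc (mean log2 5.53 in WT, 4.46 in EP2KO), Dcn (4.83, 3.00) and Col1a2 (4.32, 3.23) were far above background, and 3 of the 33 members are on other lists too. Genotype alone cannot be told apart from it: the list's slide-by-genotype difference had a camera adjusted p = 2.81e-14, but 0.561 with an estimated correlation. The slide-blocked median of -1.07 stayed below 0 without each of the 8 arrays (-1.90 without WT 2), the criterion set in advance against a single array, but it was -0.18 ± 1.02 (SE) without EP2KO 4, so after the values were seen this was left open, since it lies within its error.

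The sex-linked genes did not match the labels. Y-linked probes that failed on a few arrays are argued against, since the most arrays on which any of the 5 was well above background was 1. RNA of female animals in place of the sex in the labels is consistent with Xist on at least 8 of 8 arrays by either probe. Both genotypes showed this, so it does not part them, and no biological explanation was tested.

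The counts of calls were set against other splits of the arrays. Without a slide term 2 of the 35 splits gave at least the 2 features of the real one, so by the share of 0.05 set in advance chance cannot be excluded. The other is the split by slide, with 10066 features, which points to a structure of the samples. That verdict rests on the split by slide, and the other slide-balanced splits gave at most 0 features without a slide term. With the slide as a block, 18 splits are too few for a share under 0.05. The real one gave 4 features and the highest other 0, with 1 split reaching the real count. Among the 8 splits that part as many equal-numbered pairs as the real one, the highest other count was 0 features and 11 lists. Of the 8, 6 gave at least 5 lists, and the splits other than the real one mix genotypes. For lists, 31 of 35 splits gave at least 5, the highest other 17, so chance cannot be excluded. With the slide as a block 12 of 18 gave at least 8, the highest other 14, and these splits too are too few.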

How the results depend on the processing

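The slide-alone fits, the slide-blocked fits without 1 array, the random slide block and the slide block with an estimated correlation were chosen after seeing the data; the cause of the changes was not tested, except that fits without an array or on 1 slide hold fewer samples. Both called probes were among the calls wherever at least 2 features were called. The 2 called features became 0 with the replicate block. No named gene was called without a block, so no such call could be lost. The slide-blocked call of Ptger2 was absent with the replicate block (limma adjusted p = 0.217). The count was 4 with the slide or scan day block (the same split) and 4 with the slide as a random block (the 2, Ptger2 and Cdhr1). It was 4 at an adjusted p under 0.1, 0 on slide 1 and 340 on slide 2. Without 1 array the count ran from 0 (without WT 1, WT 3, EP2KO 2, EP2KO 3 or EP2KO 4) to 4 (without WT 4 or EP2KO 1). In the slide-blocked fit it was 0 without WT 1 or WT 3, 7 without WT 2, 6 without EP2KO 1, and 2 or 3 without the others.

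Ptger2 was lower under all 35 alternatives (-1.86 to -1.58, adjusted p 0.0122 to 0.432) and passed under 5: slide, scan day or random slide block (-1.76), quantile scaling (-1.74) and probes well above background on all 8 arrays (-1.76). The 5 lists called became 12 with normexp, 8 with quantile or median scaling, without a filter, with every probe tested or with the slide or scan day block, 11 with the replicate block, 0 with an estimated correlation or fry (lowest adjusted p = 0.798 and 0.936), 13 on slide 1, 11 on slide 2 and 1 with the slide block and an estimated correlation. Without 1 array the lists ran from 4 (without WT 1) to 12 (without EP2KO 1), with 8 without WT 3. In the slide-blocked fit they were 7 without WT 4, 8 without WT 1, 9 without WT 2 or EP2KO 2, 11 without WT 3, EP2KO 3 or EP2KO 4 and 12 without EP2KO 1.

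Large peritoneal macrophage and T and NK cell genes were called in 23 of 26 other ways of processing each. Apart from an estimated correlation and fry, the call was lost without EP2KO 2 for the first (0.22, from 0.52), without WT 1 for the second (-0.40, from -0.76), and without WT 3 (0.69) or EP2KO 2 (0.68) for eosinophil and mast cell genes. Cdhr1 passed with median scaling, array weights (whose estimation stopped before its tolerance) or the random slide block, on slide 2 alone and without WT 2 with or without the slide block.

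Some list medians turned with a call on 1 side: oxidative phosphorylation 0.030 with normexp, chemokines 0.34 and fibroblast and mesothelial genes 1.06 on slide 1 alone, and cell cycle -1.01 on slide 2 alone. For endothelial and neutrophil genes only the camera direction turned, from up: endothelial genes were called lower on slide 2 alone (-0.63, from -0.10), and neutrophil genes without EP2KO 1 (-0.57; -0.24 in the slide-blocked fit), and without 1 array their median ran from -0.57 to 0.079. Normexp moved the median of all features to -0.12 and median scaling to 0.12, from -0.03. Values of the series table were identical and test nothing. Signals near background limit Cdhr1, Samd4, Nat8f5, Itln1 and Asic5 to bounds, and Frmpd1, Slc7a11, Ccl12, Ptgdr2 and Bcl11b were near background on some arrays.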

Other observations

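All values in this part were chosen after seeing the data. Many named genes differed between the slides, for which the labels give no reason. With genotype in the model, 13 of 24 members of the inflammatory list were lower and 4 higher on slide 2 (camera adjusted p = 0.000213; adjusted p = 0.157 with an estimated correlation). Il6 was lower on slide 2 by a log2 difference of -5.11 ± 0.40 (SE, limma adjusted p = 0.000185), Acod1, the itaconate-producing enzyme, by -4.76 ± 0.30 and Il1b by -2.80 ± 0.26. The neutrophil receptors Fpr1 (-5.87 ± 0.33) and Fpr2 (-5.26 ± 0.26), the T cell gene Cd3g (-2.80 ± 0.16) and the B cell gene Cd79b (-3.17 ± 0.24) were also lower on slide 2. Higher on slide 2 were Spp1, which encodes osteopontin (4.31 ± 0.29), the chemokines Ccl3 (2.08 ± 0.24) and Ccl4 (1.66 ± 0.25), the protease Ctsk (5.21 ± 0.37), Gpnmb (4.39 ± 0.42) and the cholesterol transporter Npc1 (1.96 ± 0.10). Ccl3 and Ccl4 were the only 2 of 22 measured chemokines that passed as higher, while 7 passed as lower. By list, 16 of 28 were called and 14 were lower on slide 2, among them B cell (median -3.03), neutrophil (-2.24), large peritoneal macrophage (-2.09) and T and NK cell genes (-2.09). None held with an estimated correlation (lowest adjusted p = 0.0618). Slide and scan day coincide, and the source of these differences was not tested.

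Genes of the absorptive cells of the gut had their highest median on WT 1, while WT 3 lay within the range of the EP2KO arrays. A list of 30 such genes was written after 5 of them had been seen among the 25 named genes with the smallest p. Of the 14 other measured members, 12 were lower in EP2KO on both slides, with a median of -2.43 (-3.46 on slide 1, -1.35 on slide 2). The median per array, centred per gene, was 3.80, 0.16, -0.69 and 1.36 on WT 1 to 4 and between -1.5 and -0.66 on the EP2KO arrays. In EP2KO, 7 of the 14 were not well above background on at least 1 array, so these differences rest partly on background. Those 7 passed the filter only through WT, which favours a lower value in EP2KO, so the count of 12 is no test of direction. The hepatocyte list (7 measured) had a median of 0.11 and the exocrine pancreas list (8 measured) of -0.10.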
